A study of Homo sapiens with 4 samples.

How the data were processed

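Total RNA of PC3 cells was extracted with Trizol, labelled with biotin by a 3′ IVT amplification kit and hybridised to 1-colour Affymetrix arrays, per the labels' protocols. The labels gave 2 groups of 2 arrays, control siRNA and COUP-TFII siRNA, both at 40 nM and sampled at 48 h. The deposited values are the authors' probe set intensities on a linear scale, from 0.61 to 15890, for 54675 probe sets per array. The summary method, background correction and normalization are not given in the sources used here. Between 1088 and 1184 values per array equalled 1, as from a floor, and 31.4% to 33.0% lay below 16. The values carry no detection calls, and the number of arrays limits the precision. Array medians differed by at most 3.66%, under the limit of 5% set for further scaling, so none was applied.

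Intensities were used as log2(value + 16). Fold changes are on this scale, which understates changes of dim genes. The probe table given for the array named 1 gene for 41091 probe sets other than controls and several for 1801, and did not name 11721. The 62 control probe sets were left out of the tests. Symbols were updated through Entrez identifiers in a RefSeq gene table of GRCh38.p14, which matched 41037 of the single-gene probe sets. That table's coordinates were not used. Each gene was represented by the single-gene probe set with the highest mean over all 4 arrays, leaving out probe sets marked _x_at (open to cross-hybridisation) where the gene had another. Of the 19775 genes, 419 were still represented by an _x_at probe set and 5268 by one marked _s_at or _a_at, which can match several transcripts. Of the 4563 called genes, 3027 had more than 1 probe set, and 56 had another probe set that passed in the other direction. The target's own transcript, some members of the gene lists and the values of 1 of the 12 largest rises are not reported here.

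Group differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), without a replicate block, with Benjamini-Hochberg adjustment over all genes at a threshold of 0.05. The fit had 2 residual degrees of freedom per gene and 8.85 after moderation. In 19775 genes simulated from the control means and the fitted spread, with 200 genes changed, the test recovered 14.9% of changes of 0.5, 62.7% of changes of 1 and 98.5% of changes of 2 on the log2 scale, and 9 of 126 calls were false. Simulation without change gave 0 calls. Each setting was a single draw, with far fewer changed genes than the 4563 called here, so these rates may not carry over. Figures were drawn with matplotlib 3.10.9.

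The 30 gene lists, fixed before the data were examined, covered DNA replication, mitosis, G1 regulators, the TGF-beta response and its components, VEGF and Notch signalling, epithelial and mesenchymal markers, invasion, matrix and integrins, interferon, NF-kappaB cytokines, cholesterol and fatty acid synthesis, glycolysis, hypoxia, oxidative phosphorylation, chaperones, the ATF4 response, p53 targets, apoptosis, nuclear receptors, RNA interference, housekeeping genes and 5 sets of markers of other cell types. Lists were tested with camera (preset correlation 0.01) over all 30, with fry and with camera at an estimated correlation beside it. Camera asks whether a list differs from other genes. Fry asks whether its members move, on balance, one way. An estimated correlation rests on 2 residual degrees of freedom, and 0 of the 30 lists passed with it. For DNA replication the estimate was 0.0118, close to the preset, yet the camera adjusted p went from 7.21e-20 to 0.346. Failing this version therefore does not decide whether correlation between genes accounts for a list. Fry passed 8. In simulations camera passed 0 lists without change and 1 when 1 list was shifted. The simulated genes were drawn independently, so this does not test how camera behaves when genes are correlated.

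The rule for named genes was also fixed beforehand. It took the 12 largest rises and 12 largest falls among genes that passed, whose groups did not overlap and whose higher group lay above the median of all genes. It added up to 4 members with the largest change from each list that passed camera and from 5 lists of prior interest, and the relatives NR2F1 and NR2F6. Genes known only by a locus name were to be passed over, which removed 0. Alternatives covered the replicate block, normalization, pseudocounts of 1 and 64, dim genes, the prior variance, probe set choice, thresholds and each array left out. Centring on the mean of the housekeeping genes was added after seeing the data.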

Results

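Gene expression was measured in PC3 cells, a human prostate cancer cell line derived from a bone metastasis, 48 h after transfection with 40 nM of either a control siRNA or an siRNA against COUP-TFII, an orphan nuclear receptor that acts as a transcription factor. Each group held 2 arrays. The comparison asked which transcripts change when COUP-TFII is depleted. The 4 arrays had similar intensity distributions, with medians from 31.7 to 32.9 over 54675 probe sets. On the log2 scale, replicate arrays correlated at r = 0.9871 for control siRNA and 0.9880 for COUP-TFII siRNA across probe sets, and arrays of different groups at 0.9750 to 0.9793. The ratio of the 3′ to the 5′ control probe set of ACTB, a sign of RNA integrity, was 1.67 ± 0.22 (SD, n = 2) in the control arrays and 1.44 ± 0.03 (SD, n = 2) in the COUP-TFII siRNA arrays, without overlap. With 2 arrays against 2 an exact permutation test cannot give a two-sided p below 0.333. The same ratio for GAPDH was 0.971 ± 0.021 and 0.990 ± 0.005 (SD, n = 2). The siRNA labels were not checked against the level of the targeted transcript. The labels do not say whether replicates came from separate transfections, and the p-values measure only the spread between these arrays, which may be technical.

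COUP-TFII siRNA was followed by a broad change in expression, in which cell cycle genes fell and genes of the TGF-beta response, the extracellular matrix and integrins rose. Genes also fell in the lists of NF-kappaB cytokines (8 of 14), interferon response (11 of 26), endoplasmic reticulum chaperones (12 of 16) and cholesterol biosynthesis (9 of 16). With an estimated correlation none of the 30 lists passed camera (adjusted p of 0.346 for DNA replication, 0.69 for cytokines and 0.638 for the other lists named here). That version rests on 2 residual degrees of freedom and does not decide whether correlation between genes accounts for a list. Of 19775 genes tested, 4563 (23.1%) passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 2524 of them higher and 2039 lower. More falls than rises reached 2-fold, 333 against 181. At 1.5-fold the counts were nearly even, 906 lower and 913 higher. The median log2 fold change of all genes was 0.01. The COUP-TFII siRNA arrays were also those with the lower ACTB 3′ to 5′ ratio, although their GAPDH ratio was not lower. The count depended on the estimate of the spread. It was 767 higher and 822 lower with 1 prior variance for all genes, and 1059 and 875 without control replicate 1, 865 and 927 without control replicate 2, 969 and 1373 without COUP-TFII siRNA replicate 1, and 1231 and 1131 without COUP-TFII siRNA replicate 2. Centring on the median of housekeeping genes moved the median of all genes up by 0.23. It took the median log2 fold change of the housekeeping genes themselves from −0.05 to 0.17, a shift larger than their own change. The split was then 6335 higher and 1130 lower (84.9% higher, against 55.3%). Centring on the mean of housekeeping genes gave 3664 higher and 1586 lower.

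**Figure D1:**
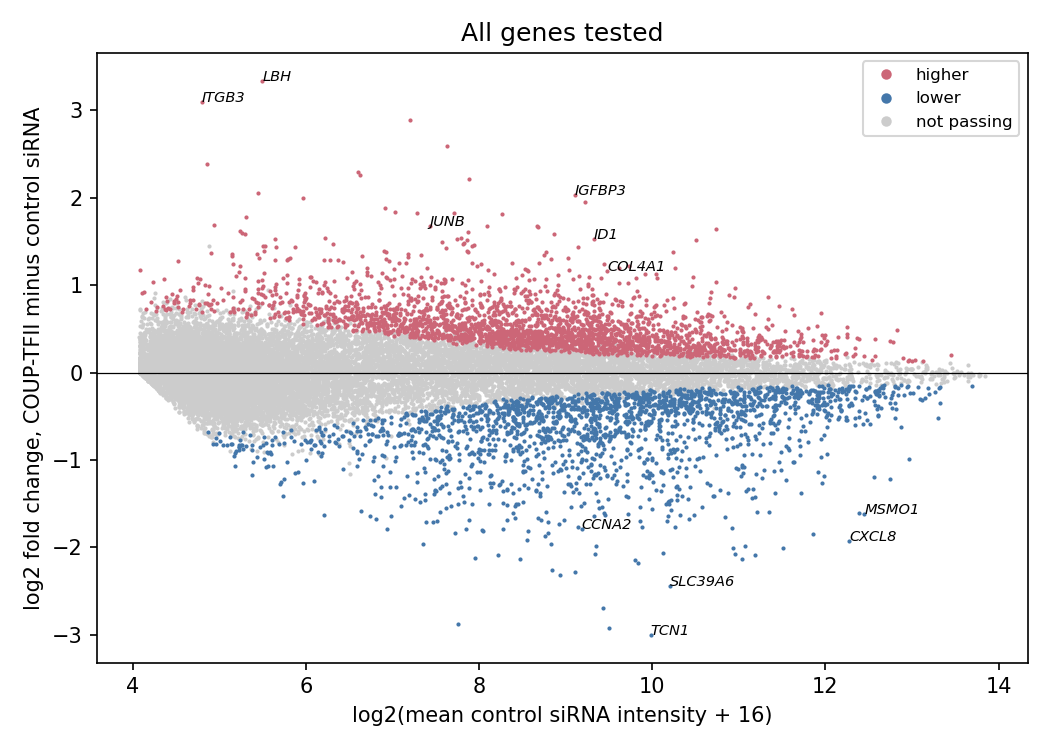
Each point is 1 of the 19775 genes tested, with the log2 of the mean control siRNA intensity plus 16 on the x axis and the log2 fold change (COUP-TFII siRNA minus control siRNA, 2 arrays each) on the y axis. Colours mark the 2524 genes that were higher and the 2039 that were lower at a limma adjusted p under 0.05, and grey marks the rest.

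Among the largest rises, LBH, which encodes a transcription cofactor, went from an intensity of 29.1 ± 14.4 to 430.3 ± 52.0 (SD, n = 2), a log2 fold change of 3.34 ± 0.21 (SE; limma adjusted p = 1.08e-05). ITGB3, the integrin beta-3 subunit, rose from 11.8 ± 2.5 to 220.4 ± 7.5, a log2 fold change of 3.09 ± 0.17 (SE; limma adjusted p = 6.14e-06), with 3 of its 7 probe sets passing. SCG5, a chaperone of a prohormone convertase, rose from 131.4 ± 18.6 to 1073 ± 141. MYL9, a myosin regulatory light chain, rose by 2.29 ± 0.14 on the log2 scale and IGFBP3, a binding protein of insulin-like growth factors, by 2.03 ± 0.07. The kinase gene STK38L rose from 580.0 ± 21.7 to 2296 ± 177, the chloride channel family member CLIC3 from 46.3 ± 1.4 to 233.5 ± 18.0 and TCIM from 13.0 ± 0.7 to 139.8 ± 49.6. The 12 largest rises held 3 long non-coding RNAs. UCA1 rose from 219.4 ± 23.4 to 1078 ± 88, APCDD1L-DT from 83.0 ± 15.4 to 456.5 ± 36.1 and LINC01607 from 27.7 ± 2.9 to 165.4 ± 20.4. All 12 had limma adjusted p-values of 0.000141 or less and kept their direction and their call in the 15 alternatives fitted for single genes. Their direction with an array left out was fixed by the selection, which took only genes whose groups did not overlap. A plain t statistic, without moderation, called 0 genes after adjustment. Averaging a gene's probe sets lowered the log2 fold change to 1.06 for ITGB3, 1.25 for MYL9 (1 of 2 probe sets passing), 1.15 for LINC01607 and 0.84 for APCDD1L-DT (1 of 3 passing). Adding 64 in place of 16 before the logarithm gave 1.91 for ITGB3, 1.38 for TCIM and 1.32 for LINC01607.

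Among the largest falls, TCN1, a vitamin B12-binding protein, went from 995.4 ± 169.2 to 110.1 ± 16.6 (SD, n = 2), with log2 fold changes from −3.17 to −2.83 when 1 array was left out (limma adjusted p = 2.17e-06 with all arrays). PHTF2 fell from 708.7 ± 38.1 to 80.0 ± 2.2, although only 1 of its 5 probe sets passed. FOXA2, a forkhead transcription factor of endodermal tissues, went from 201.0 ± 17.6 to 14.4 ± 10.1, a log2 fold change of −2.87 ± 0.24 (SE; limma adjusted p = 4.67e-05), with 1 of 3 probe sets passing. The zinc transporter gene SLC39A6 went from 1162 ± 60 to 201.1 ± 4.0 with all 4 of its probe sets passing, and the phosphodiesterase gene PDE1C from 474.9 ± 38.0 to 82.5 ± 0.1 with 4 of 6. GNB4, a G protein beta subunit, fell from 674.6 ± 79.1 to 91.1 ± 9.9 and TAF9B, a subunit of general transcription complexes, from 873.0 ± 54.5 to 186.0 ± 15.4. CCDC50 fell from 2081 ± 34 to 463.5 ± 25.3. Of the 12 largest falls, GINS2, part of the replicative helicase, DTL, an adaptor for ubiquitination of the replication licensing factor CDT1, and DEPDC1 belong to cell division. GINS2 fell from 443.0 ± 27.0 to 80.9 ± 19.8, DTL from 339.6 ± 20.9 to 65.4 ± 8.1 and DEPDC1 from 537.2 ± 80.8 to 97.5 ± 15.2. The membrane glycoprotein gene PROM2 fell from 897.8 ± 52.0 to 186.2 ± 11.1 on its brightest probe set, with 1 of 5 passing, and fell by 0.40 on the log2 scale when its probe sets were averaged (limma adjusted p = 0.0608, against at most 0.00452 with any array left out). Averaging probe sets also moved the log2 fold change to −0.76 for PHTF2, −1.05 for FOXA2, −1.26 for GNB4, −1.49 for PDE1C, −0.97 for GINS2 and −0.81 for TAF9B, and adding 64 gave −1.76 for FOXA2.

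**Figure D2:**
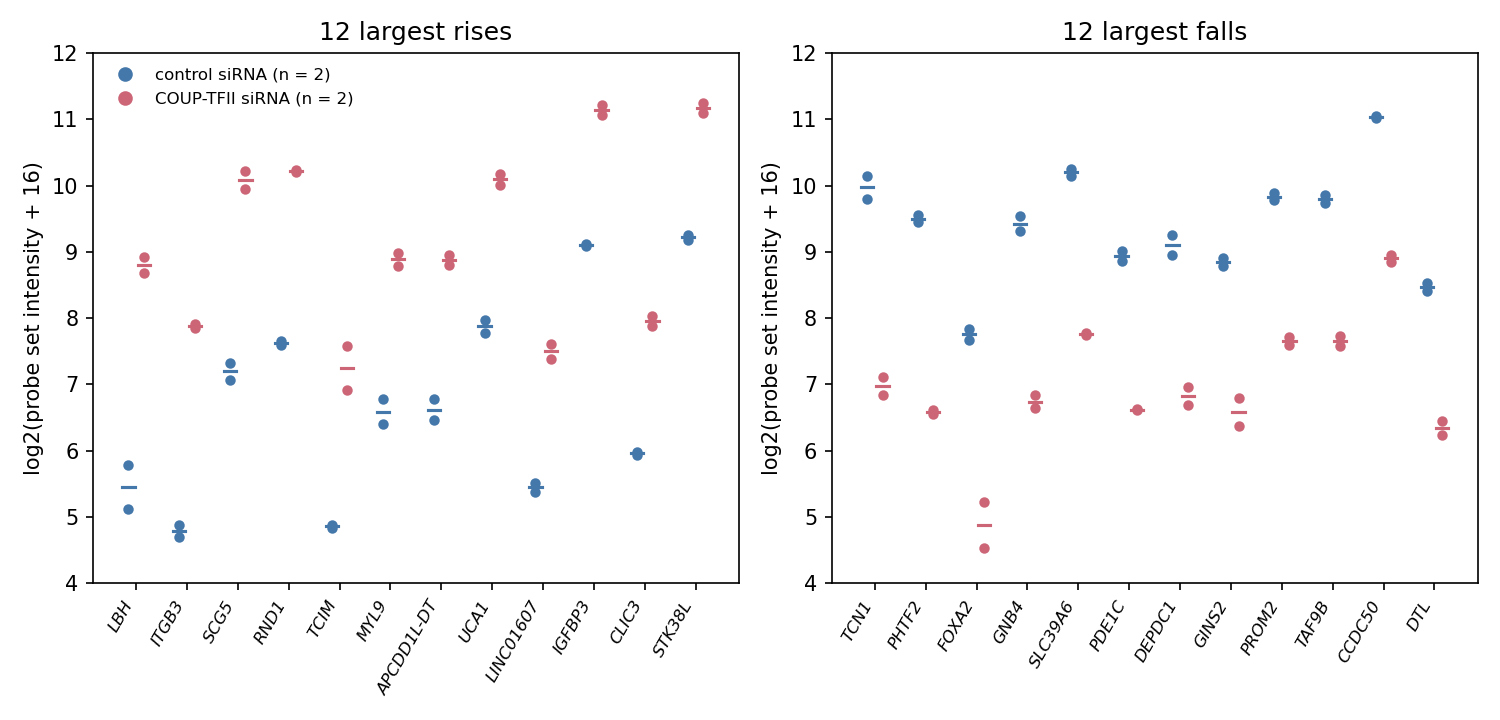
Points are single arrays (control siRNA and COUP-TFII siRNA, n = 2 each) and short lines group means, on the log2 of the probe set intensity plus 16, for the 12 genes with the largest rise (left) and the 12 with the largest fall (right). The groups do not overlap for any of the 24 genes, a condition of their selection. LBH and TCN1 show the largest rise and fall.

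Genes of cell division fell as a group. All 36 measured genes of the G2/M and mitosis list fell, with a median log2 fold change of −1.30 (interquartile range −1.51 to −1.06). NUF2, a kinetochore component, fell from 429.3 ± 66.2 to 108.1 ± 0.9 (SD, n = 2), CCNA2, the cyclin of S and G2 phase, from 566.1 ± 35.4 to 151.7 ± 4.8, the mitotic kinase gene AURKB from 429.4 ± 10.8 to 123.0 ± 38.9 and the spindle checkpoint kinase gene TTK from 490.0 ± 3.3 to 141.1 ± 11.5. AURKB had 1 of 2 probe sets passing, and its log2 fold change of −1.71 was −0.55 when they were averaged (limma adjusted p = 0.047, the highest of all alternatives, from 7.33e-20). FOXM1, a transcription factor of G2/M genes, MKI67, the Ki-67 proliferation antigen, and CENPF, a centromere protein, which were picked out after their values were seen, fell by 0.63, 0.98 and 0.92 on the log2 scale. Of 31 genes of DNA replication and S phase, 25 fell, 1 rose and 5 did not pass, with a median of −0.91 (26 lower and 1 higher adjusted over the list alone). Beside GINS2, the DNA polymerase epsilon subunit gene POLE2 fell by 1.80 ± 0.19, the origin licensing gene CDC6 by 1.71 ± 0.20 and MCM10 by 1.68 ± 0.20 (SE, log2 scale). Adding 64 before the logarithm left falls of 1.11 for CDC6 and 0.95 for MCM10. The 1 that rose, also named after its value was seen, was CCNE1, the G1/S cyclin E1, at 0.81 ± 0.10. Both lists were lower than other genes by camera with the preset correlation (adjusted p = 1.02e-35 for G2/M and mitosis and 7.21e-20 for replication). With an estimated correlation, 0.486 for the first list and 0.0118 for the second, the camera adjusted p-values were 0.638 and 0.346. Median changes of 10000 random lists matched on expression lay between −0.09 and 0.19 for the first list. For the second they lay between −0.11 and 0.19 (2.5th to 97.5th percentile for both). Random members were drawn independently, so these ranges take no account of correlation between the genes of a list. The ACTB 3′ to 5′ ratio was lower in the COUP-TFII siRNA arrays in which these lists fell, while the GAPDH ratio was not.

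The G1 regulators moved in both directions. CDK6, a cyclin D-dependent kinase, fell from 928.2 ± 217.8 to 257.4 ± 9.2 (SD, n = 2), with 3 of 7 probe sets passing and a log2 fold change of −1.77 that was −0.85 when they were averaged, the growth regulator MYC from 1473 ± 31 to 740.6 ± 7.9 and CDKN1B, the inhibitor p27, from 1143 ± 91 to 703.1 ± 61.8. CDKN1A, the inhibitor p21, rose from 835.6 ± 60.2 to 1960 ± 27, a log2 fold change of 1.22 ± 0.07 (SE; limma adjusted p = 5.15e-06). The other gene that rose, CDKN1C, named after its value was seen, was higher by 0.31. Of 16 measured genes, 7 fell, 2 rose and 7 did not pass, both over all genes and adjusted over the list alone. The list median of −0.23 gave a camera adjusted p of 0.0333, which was 0.69 with an estimated correlation, 0.123 without control replicate 1 and 0.0796 without COUP-TFII siRNA replicate 2, within a range of 0.0173 to 0.143 over the alternatives of the fit.

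Genes of the TGF-beta response rose. Of 24 measured genes, 17 rose, 1 fell and 6 did not pass, with a median log2 fold change of 0.58 (18 higher and 1 lower adjusted over the list alone). JUNB, an AP-1 transcription factor, rose from 156.7 ± 4.3 to 536.2 ± 16.5 (SD, n = 2), ID1, an inhibitor of DNA binding, from 626.6 ± 10.5 to 1832 ± 46 and SMAD7, the inhibitory SMAD, from 34.4 ± 0.0 to 120.7 ± 11.4, where the log2 fold change of 1.44 was 0.91 with 64 added before the logarithm. CDKN1A is also in this list. KLF10, the 1 that fell and named after its value was seen, changed by −0.20 ± 0.06 (SE, limma adjusted p = 0.0487). The camera adjusted p was 1.92e-08 with the preset correlation, and the adjusted p was 0.638 with an estimated correlation. The pathway's own components did not move together: 3 of 14 rose, 3 fell and 8 did not pass (camera adjusted p = 0.847). Among these 6, picked out after their values were seen, TGFB1 (0.73), ACVR1B (0.51) and SMAD3 (0.48) were higher, and LTBP1 (−1.54), the receptor gene TGFBR2 (−1.02) and BMPR2 (−0.59) lower, on the log2 scale. When all probe sets were tested, 0 of the 6 BMPR2 probe sets passed as lower and 1 passed as higher.

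Extracellular matrix and integrin genes rose, 12 of 20, with 1 lower and 7 not passing and a median of 0.44, which was 0.66 after centring on the median of housekeeping genes (14 higher and 2 lower adjusted over the list alone). Besides ITGB3, the basement membrane collagens COL4A2 and COL4A1 rose by 1.24 ± 0.08 and 1.16 ± 0.06 (SE, log2 scale), and ITGB4 rose from 617.5 ± 31.2 to 1211 ± 40 (SD, n = 2), a log2 fold change of 0.95 that was 0.51 with averaged probe sets. ITGA6, the integrin alpha-6 subunit and the 1 that fell, changed by −0.78 ± 0.05 and was named after its value was seen. COL4A1 and FN1 are also in the TGF-beta response list. The camera adjusted p was 4.93e-06 with the preset correlation, and the adjusted p was 0.638 with an estimated correlation. In the invasion and proteolysis list 7 of 20 rose, 1 fell and 12 did not pass, with a median of 0.20, or 0.42 after that centring and 0.13 to 0.28 with 1 array left out (9 higher and 1 lower adjusted over the list alone). The cathepsin gene CTSB rose from 1030 ± 7 to 1758 ± 5 and the gelatinase gene MMP9 from 630.8 ± 31.9 to 966.4 ± 90.3. MMP7 and CTSD also passed, at log2 fold changes of 0.94 ± 0.23 and 0.37 ± 0.07, MMP7 at 0.50 with 64 added before the logarithm and CTSD at 0.60 after that centring. MMP9 had a limma adjusted p of 0.0569 with 1 prior variance for all genes, the highest of all alternatives, from 2.31e-08. MMP7 did not pass with any array left out (limma adjusted p = 0.0623 to 0.19), nor CTSD without either control array (limma adjusted p = 0.0704 without replicate 1 and 0.0685 without replicate 2, in a range over all alternatives of 2.77e-05 to 0.0788). The 1 that fell was PLAUR, the urokinase receptor gene, at −0.31, named after its value was seen. The camera adjusted p of this list was 0.0177, and the adjusted p was 0.713 with an estimated correlation. It was 0.129 with dim genes left out, the highest of the alternatives of the fit, which began at 0.00277.

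Inflammatory and interferon genes fell. Among NF-kappaB cytokines, 8 of 14 fell, 1 rose and 5 did not pass, over all genes and adjusted over the list alone, with a median of −0.44, which was −0.21 after centring on the median of housekeeping genes. The chemokine gene CXCL8 fell from 4947 ± 336 to 1295 ± 141 (SD, n = 2), IL6 from 2078 ± 113 to 990.9 ± 25.6 and CXCL1 from 3329 ± 224 to 1729 ± 137. The log2 fold change of CXCL8, −1.92, was −1.02 when probe sets open to cross-hybridisation (_x_at) were allowed. CCL20 fell by 0.83 ± 0.20 (SE, log2 scale). Of the 4 fits with 1 array left out, it passed only in the fit without control replicate 1 (limma adjusted p = 0.0415 to 0.196 over these fits). IL1A, the 1 that rose and named after its value was seen, was higher by 0.73 ± 0.20. The camera adjusted p was 9.97e-05 with the preset correlation, and the adjusted p was 0.69 with an estimated correlation. In the interferon response list 11 of 26 fell, 1 rose and 14 did not pass, with a median of −0.39, which was −0.16 after that centring (12 lower and 2 higher adjusted over the list alone). CXCL10 fell from 163.5 ± 8.7 to 54.9 ± 13.8, OAS3, a sensor of double-stranded RNA, from 506.7 ± 31.1 to 200.5 ± 18.6 and the antiviral GTPase gene MX2 from 135.5 ± 7.6 to 61.0 ± 2.9. The log2 fold change of OAS3, −1.27, was −0.82 with averaged probe sets. MX2 had a limma adjusted p of 0.0508 without control replicate 2, in a range over all alternatives of 1.37e-07 to 0.0508. CCL5 passed as higher, near the floor at 10.5 ± 1.7 and 28.0 ± 6.2, and did not pass with any array left out (limma adjusted p = 0.0962 to 0.195). The camera adjusted p was 9.97e-05, and the adjusted p was 0.638 with an estimated correlation.

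Genes of lipid synthesis and chaperones fell, and glycolysis genes moved in both directions. In cholesterol biosynthesis 9 of 16 measured genes fell and none rose, over all genes and adjusted over the list alone, with a median of −0.23 and a mean of −0.40. The median was −0.0042 after centring on the median of housekeeping genes. MSMO1, a sterol demethylation enzyme, fell from 5573 ± 168 to 1807 ± 27 (SD, n = 2), the sterol carrier gene STARD4 from 504.4 ± 3.6 to 213.8 ± 0.9, INSIG1, a sterol-regulated inhibitor of SREBP processing, from 4025 ± 61 to 1777 ± 201 and ACAT2 from 1994 ± 50 to 1288 ± 48. In fatty acid synthesis 6 of 10 fell and none rose (7 lower adjusted over the list alone), with a median of −0.40, which was −0.18 after that centring and −0.17 with averaged probe sets. The elongase gene ELOVL6 fell by 1.33 ± 0.11 (SE, log2 scale), or 0.59 with averaged probe sets. ELOVL5 fell from 4801 ± 85 to 3377 ± 159, a log2 fold change of −0.51, with 1 of 4 ELOVL5 probe sets passing. When these were averaged the change was −0.15 (limma adjusted p = 0.298, in a range over all alternatives of 4.37e-14 to 0.298). SREBF1 and FADS2 passed at −0.51 ± 0.12 and −0.43 ± 0.08. Leaving out 1 array ended the SREBF1 call in 3 of 4 cases and the FADS2 call in 3 of 4 (highest limma adjusted p = 0.16 for SREBF1, where the change was −0.34 without COUP-TFII siRNA replicate 1, and 0.0961 for FADS2). Neither passed with averaged probe sets (−0.29 and −0.20), after that centring (−0.28 and −0.21) or with 1 prior variance for all genes, and their limma adjusted p ran over all alternatives from 0.000101 to 0.416 and from 8.41e-05 to 0.185. Of 16 endoplasmic reticulum chaperone and unfolded protein response genes, 12 fell and none rose, over all genes and adjusted over the list alone, with a median of −0.40, which was −0.17 after that centring. SDF2L1 fell by 0.89 ± 0.08, CRELD2 by 0.64 ± 0.07, the chaperone gene HSP90B1 by 0.61 ± 0.09 and the disulfide isomerase gene PDIA6 by 0.55 ± 0.06 (SE, log2 scale). HSP90B1 did not pass without control replicate 1 or without COUP-TFII siRNA replicate 2 (limma adjusted p = 0.0632 and 0.0604, in a range over all alternatives of 1.84e-10 to 0.0816), nor did PDIA6 with 1 prior variance (limma adjusted p = 0.0529, the highest of all alternatives, from 4.52e-15). In glycolysis 7 of 19 fell, 2 rose and 10 did not pass (10 lower and 2 higher adjusted over the list alone), and the median of −0.18 became 0.04 after centring on the median of housekeeping genes, where camera gave an adjusted p of 0.496. LDHB fell from 5603 ± 146 to 4069 ± 216, PFKP from 1405 ± 1 to 1056 ± 114 and LDHA from 10231 ± 138 to 8013 ± 277, while PFKFB3 rose from 491.3 ± 34.3 to 681.9 ± 23.7. HK1, the other gene that rose and named after its value was seen, was higher by 0.26. With 1 prior variance for all genes LDHB and LDHA did not pass (limma adjusted p = 0.0661 and 0.0924, the highest of all alternatives, from 1.5e-13 and 7.13e-14), and after that centring they fell by 0.24 and 0.13. PFKP did not pass without either control array, at a log2 fold change of −0.41 in each fit. With averaged probe sets it did not pass either, at −0.08 (limma adjusted p = 0.785, the highest of all alternatives, from 8.29e-06). PFKFB3 did not pass without control replicate 2 or without COUP-TFII siRNA replicate 1 (limma adjusted p = 0.0654 and 0.058, in a range over all alternatives of 1.03e-05 to 0.0735). The camera adjusted p-values with the preset correlation were 5.48e-06 for cholesterol biosynthesis, 0.000196 for fatty acid synthesis, 2.3e-07 for chaperones and 0.00385 for glycolysis. With an estimated correlation all 4 had an adjusted p of 0.638.

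**Figure D3:**
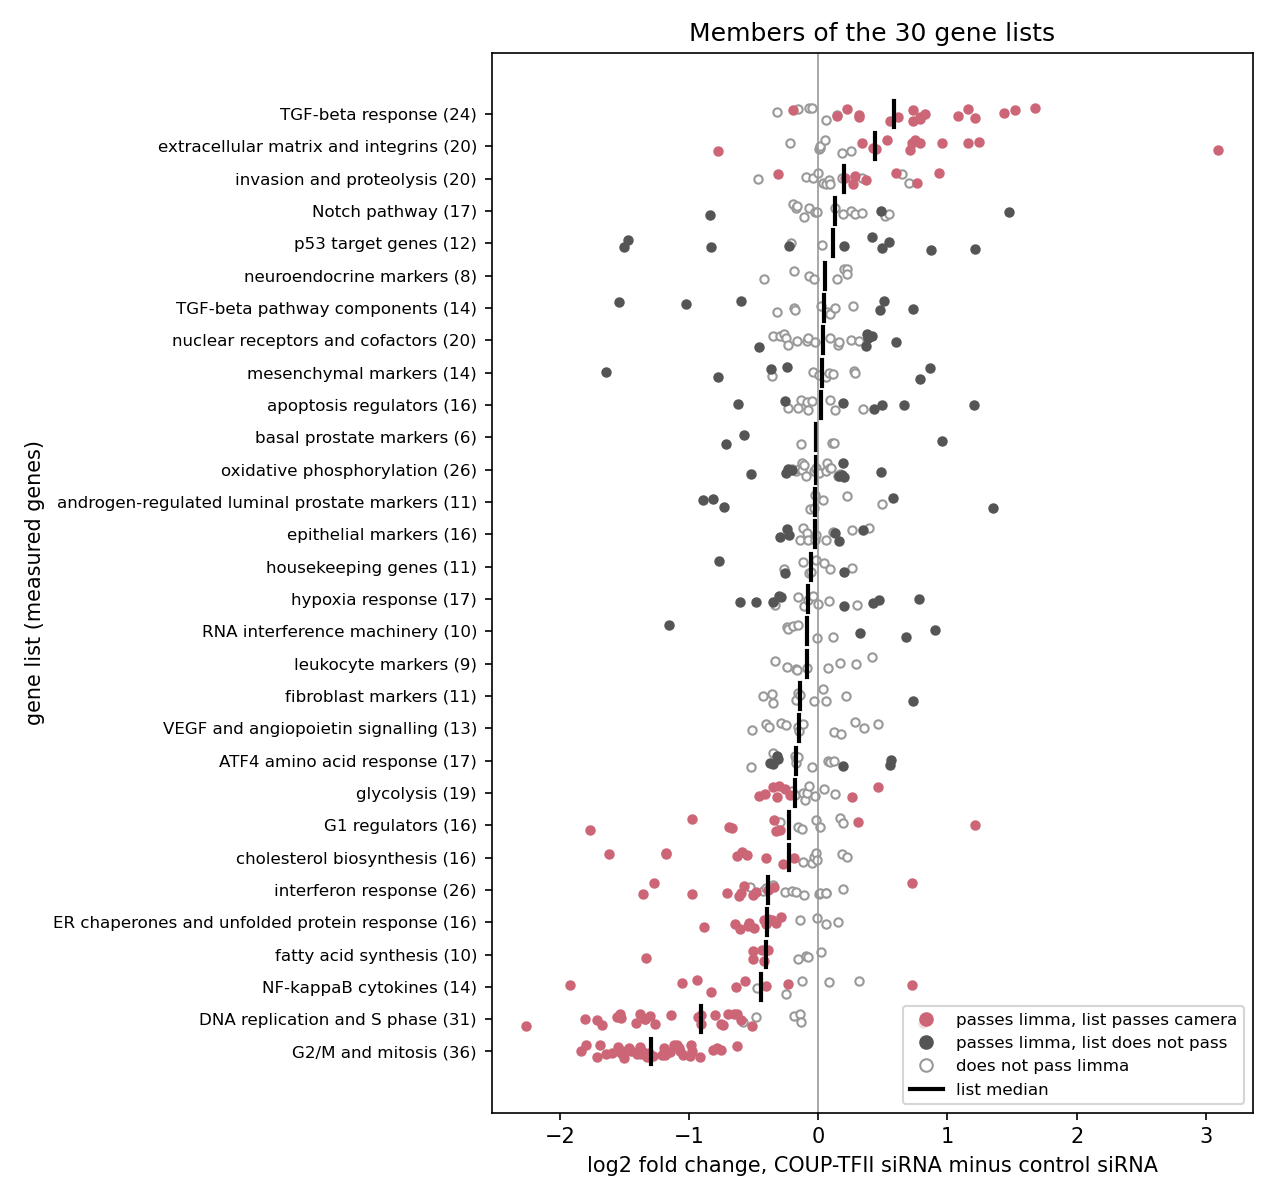
Each point is a measured member of 1 of the 30 gene lists, with its log2 fold change (COUP-TFII siRNA minus control siRNA, 2 arrays each) on the x axis. Black bars are list medians, filled points passed limma at an adjusted p under 0.05, and red marks the 12 lists that passed camera with the preset correlation, from G2/M and mitosis with a median of −1.30 to the TGF-beta response with 0.58.

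The other 18 lists did not pass camera. In VEGF and angiopoietin signalling none of 13 genes passed limma, over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05). VEGFA measured 2042 ± 58 and 1828 ± 30 (SD, n = 2; limma adjusted p = 0.0621) and VEGFB 85.3 ± 7.9 and 123.2 ± 0.2 (limma adjusted p = 0.0533). VEGFB passed as higher in 6 of its 15 alternatives (limma adjusted p = 0.00321 to 0.235 over all) and VEGFA as lower in 2 of 15 (limma adjusted p = 0.0335 to 0.518 over all). Where 5 or fewer genes of a list passed in a direction they are named in what follows, chosen after their values were seen. Of 17 Notch pathway genes HEY1 and MAML1 rose and DLL3 fell. Of 16 epithelial markers KRT8, KRT18 and ELF3 rose and CDH1, EPCAM and CLDN4 fell, and of 14 mesenchymal markers FN1 and CDH2 rose and SPARC, CDH11, VIM and TWIST1 fell. Of 17 hypoxia genes ADM, ANKRD37, PFKFB4 and KDM3A rose and PDK1, P4HA2, P4HA1, BNIP3 and NDRG1 fell. Of 26 oxidative phosphorylation genes NDUFA8, SDHA, UQCRC1, UQCRC2 and COX5B rose and CYCS, ATP5F1B, NDUFV2 and SDHD fell. Of 17 genes of the ATF4 amino acid response ATF3, CHAC1 and SHMT2 rose and PSAT1, SLC3A2, PHGDH and MTHFD2 fell. Among 12 targets of p53, which PC3 cells lack, 6 rose and PHLDA3, MDM2, FAS and TP53INP1 fell. Of 16 apoptosis regulators XIAP, BAK1, BAX, CASP9 and MCL1 rose and BCL2A1 and BCL2L1 fell, and of 10 genes of the RNA interference machinery AGO1, AGO4 and XPO5 rose and DICER1 fell. Of 20 nuclear receptors and cofactors PPARA, RXRB, NR2C2, NR2C1 and RXRA rose. The 1 that fell was NR2F1, a close relative of COUP-TFII, from 3185 ± 73 to 2318 ± 177 (limma adjusted p = 0.000685, and 0.0755 with 1 prior variance for all genes, the highest of all alternatives, from 5.55e-10). The relative NR2F6 measured 1784 ± 76 and 1756 ± 109 (limma adjusted p = 0.856), and passed as higher, at 0.20 on the log2 scale, after centring on the median of housekeeping genes (limma adjusted p = 0.00904, in a range over all alternatives to 0.991). Among 11 androgen-regulated luminal markers TMPRSS2 and HOXB13 rose and FKBP5, SLC45A3 and STEAP2 fell, and among 6 basal markers ITGB4 rose and CD44 and KRT15 fell. Among 11 fibroblast markers COL1A1, which is also in the TGF-beta response list, rose, and none of 9 leukocyte or 8 neuroendocrine markers passed limma (0 of either at an unadjusted p under 0.05). Of 11 housekeeping genes SDHA rose and HPRT1 and PGK1 fell, HPRT1 by 0.77 ± 0.06 (SE, log2 scale). Centring on the median of housekeeping genes adds 0.23 to every log2 fold change, so falls smaller than that, such as those of SDHD, TP53INP1 and KLF10, and the value of VEGFA turned sign under it. The median, mean and camera direction did not share a sign for the TGF-beta pathway components, the epithelial, mesenchymal, luminal and neuroendocrine markers, the p53 targets and the RNA interference machinery.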

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

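The tests of normalization, for both patterns, and of other cell types were chosen only after the lists' results were seen. The test of other cell types first used fibroblast and leukocyte markers, of which only 1 of 20 lay above the median gene, and was then moved to the epithelial list. No group had enough arrays for an outlier test.

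A signal was present in probe sets outside the comparisons. Among probe sets that name no gene here, 241 were higher and 195 lower in the COUP-TFII siRNA arrays when all probe sets were tested (limma, adjusted p under 0.05). Among those that name several genes, 160 were higher and 114 lower.

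The mitosis and DNA replication lists fell, with medians of −1.30 and −0.91. A normalization difference of the size tried is argued against as the whole cause. The higher of the medians was still −0.68 under quantile normalization or housekeeping centring. A centring moves all genes alike, so it tests only an even shift between arrays. It cannot change the distance of these lists from other genes. The ACTB 3′ to 5′ ratio was lower in the COUP-TFII siRNA arrays, which by this measure had less excess of 3′ signal than the control arrays. The GAPDH ratio was not lower (0.990 ± 0.005 against 0.971 ± 0.021 in the control arrays, SD, n = 2). Of all probe sets of the members above the median intensity, 99.0% fell, past the share predicted without a 3′ bias. The count includes the probe sets by which the lists were seen to fall. It also includes genes with a single probe set, which cannot go both ways. The share was thus largely fixed beforehand and does not decide about a 3′ bias. A quality difference that lowers all probe sets of a gene would look the same, so RNA quality stays open. Non-epithelial cells in the COUP-TFII siRNA cultures are argued against as the whole cause, since they would dilute the epithelial list about as much, and its median was −0.0239 (interquartile range −0.12 to 0.14), while other epithelial cells were not tested. Off-target silencing by the duplex cannot be told apart from depletion of COUP-TFII, since 0 arrays of a second, independent duplex are in the labels, and a slower cell cycle after COUP-TFII depletion stays open as a hypothesis.

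The interferon list fell, with a median log2 fold change of −0.39. A normalization difference was not excluded: the median was −0.39 under quantile normalization but −0.16 after centring on the median of housekeeping genes, between the bound of −0.2 set for excluding it and the bound of −0.1 set for accepting it. A restatement relative to the median of all genes was tried once this was seen and was dropped. A centring moves all genes alike and cannot change that difference. The housekeeping centring took the housekeeping genes' own median log2 fold change from −0.05 to 0.17. The value of −0.16 therefore rests on a shift larger than these genes' own change. A response to the control duplex that the other duplex lacked cannot be told apart from a loss of basal interferon signalling after COUP-TFII depletion, because the labels hold 0 untransfected or mock-transfected arrays. All of these stay open.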

How the results depend on the processing

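Of the named genes' values under the alternatives, 1030 kept their direction and their side of the threshold, 51 no longer passed, 8 newly passed in the same direction (VEGFB and VEGFA), 4 passed in neither fit and had the other sign, and 1 newly passed in the other direction (NR2F6, at 0.20 under the housekeeping median). For the gene lists, 361 values kept both, 8 no longer passed, 46 passed in neither fit and had the other sign, and 2 turned direction across the threshold (glycolysis and oxidative phosphorylation). With the replicate block, 2858 genes were higher and 2274 lower. The numbers did not pair the arrays (correlation of same-numbered deviations 0.018 across genes), and the block ended no call of a list. Counts of genes moved by over 1.5 times under these settings: centring on the median of housekeeping genes gave 6335 higher and 1130 lower, 1 prior variance for all genes 767 and 822, the mean of a gene's probe sets 1631 higher, an adjusted p under 0.01 1457 and 1324, and a change of at least 1.5-fold 913 and 906. All probe sets gave 3094 lower, and the plain t statistic 0 and 0 after adjustment (4596 at an unadjusted p under 0.05, against 6457 with limma). Leaving out 1 array gave 865 to 1231 higher and 875 to 1373 lower. The smaller counts with an array left out come with 1 residual degree of freedom less, and the cause of the others was not tested. Of the 4563 calls, none changed sign with an array left out, and 136 did so after housekeeping centring and 135 with averaged probe sets. The housekeeping median is the level of 1 gene per array. Centring on the housekeeping mean gave 3664 higher and 1586 lower. The G1 regulators' median stopped passing at −0.0016 under housekeeping centring (camera adjusted p = 0.101), at −0.23 with dim genes left out (0.0526) and with 1 prior variance (0.0768), and at −0.11 with averaged probe sets (0.143), and ranged from −0.28 to −0.16 with an array left out. The invasion median stopped passing at 0.14 with dim genes left out. The glycolysis median turned to 0.043 under the housekeeping median and stopped passing at −0.095 under the housekeeping mean (0.0586). The cause was not tested. Oxidative phosphorylation passed as higher only under the housekeeping median (0.21, camera adjusted p = 0.0159, in a range to 0.925). The other 9 lists that passed camera did so under all alternatives of the fit, although the cholesterol median was −0.0042 under the housekeeping median. No list passed with an estimated correlation (adjusted p from 0.346). With fry the G1 regulators (0.127), invasion (0.127), interferon (0.136), cytokine, glycolysis and chaperone lists (0.0746 each) did not pass, while the Notch list (0.0245) and the p53 targets (0.0412) passed with fry only, and with camera on ranks the G1 regulators (0.0786) did not. Intensities near the floor limit the dim genes, since the values carry no detection calls.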

Other observations

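The 8 gene lists of this part were written after the largest single-gene changes had been seen, among them HJURP, NCAPH, CENPM, FANCI, ID3, MYL9 and EPPK1, so all tests in this part count as chosen after results were seen. The bounds were also changed once the list values were known. By the first bounds, which overlapped, the YAP and SRF and the lysosomal lists had met their predictions and the BMP and ID list had failed its own. The predictions decide nothing for the 5 lists that hold a gene seen beforehand, since those genes prompted the lists. The p-values are adjusted over the 8 lists.

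Structural genes of the mitotic chromosome fell with the mitosis list. Of 27 measured genes of condensin, cohesin and the centromere, 23 fell and none rose, with a median log2 fold change of −0.94 (camera adjusted p = 9.25e-21, and an adjusted p of 0.117 with an estimated correlation). HJURP, the chaperone of the centromeric histone, fell by 1.81, the condensin gene NCAPH by 1.79 and CENPM by 1.79. Without these 3 genes the median was −0.88. Among cohesin subunit genes, SMC1A fell by 0.98 with 1 of its 4 probe sets passing. SMC3 (−0.22) and RAD21 (−0.14) did not pass. Of 21 genes of the Fanconi and homologous recombination pathways, 12 fell and none rose, with a median of −0.49 (camera adjusted p = 8.51e-07, and an adjusted p of 0.117 with an estimated correlation). FANCI fell by 1.87 and the exonuclease gene EXO1 by 1.71, and without FANCI the median was −0.46. With all members it was −0.26 after centring on the median of housekeeping genes. Of 24 nuclear pore genes 10 fell and 2 rose, with a median of −0.25 (camera adjusted p = 8.05e-05, and an adjusted p of 0.124 with an estimated correlation), which was −0.02 after centring on the median of housekeeping genes. Of 25 cytosolic ribosomal protein genes 0 passed limma (0 at an unadjusted p under 0.05). The median was −0.0034 (SE 0.0128, from a bootstrap over members), and 0.22 after centring on the median of housekeeping genes. That SE does not measure the spread between arrays or an error of scaling. Both medians argue against a fall of 0.2 or more on the log2 scale in these genes. Their median control intensity of 9577 lay near the top of the scale. A rule that voided the test for this alone was relaxed once falls at such levels were seen: 15 of 94 genes above a control intensity of 7945 were lower (limma, adjusted p under 0.05), by up to 0.99. The 5 ribosomal genes below that intensity and above the median gene changed by −0.03 to 0.06, where 43 of 106 genes as bright were lower. Smaller falls stay open.

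Of 14 keratin and desmosome genes 7 rose and none fell, with a median of 0.28 (camera adjusted p = 3.8e-05, and an adjusted p of 0.117 with an estimated correlation). The cytolinker gene EPPK1 rose by 1.84, and the plakin genes EVPL and PPL by 0.64 and 0.60. Without EPPK1 the median was 0.20, and with all 14 genes it was 0.50 after centring on the median of housekeeping genes. Lysosomal genes had 9 of 20 higher and 3 lower, with a median of 0.15 (camera adjusted p = 0.0179, and an adjusted p of 0.179 with an estimated correlation). This was under the size of 0.2 that a predicted rise had to reach. The median was 0.37 after centring on the median of housekeeping genes, so missing that size depended on the scaling. YAP and SRF target genes had 7 of 18 higher and 2 lower, also with a median of 0.15 (camera adjusted p = 0.0179, and an adjusted p of 0.494 with an estimated correlation). Their median was 0.38 after that centring. MYL9 and ANKRD1 rose by 2.29 and 1.05, while AXL, a receptor tyrosine kinase gene, fell by 1.44. BMP and ID genes had 3 of 14 higher and 2 lower, with a median of 0.17 (camera adjusted p = 0.241). ID3 and ID1 rose by 1.88 and 1.52, and SMAD6, an inhibitory SMAD gene, fell by 0.98.

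Lists that did not pass camera held some large single-gene changes, picked out after their values were seen. The Notch effector HEY1 measured a mean of 209.5 in the control arrays and 612.1 in the COUP-TFII siRNA arrays, XIAP, an inhibitor of caspases, 767.5 and 1785, and the androgen-regulated protease gene TMPRSS2 144.3 and 391.6. DICER1, which processes small RNAs, measured 448.2 and 191.9, MDM2, a regulator of p53, 649.3 and 224.3, and the matrix protein gene SPARC 110.4 and 24.6 (limma adjusted p under the threshold for all 6). The collagen gene COL1A1, the only fibroblast marker that passed, measured 569.5 and 955.6.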
